A study of Medicago truncatula with 2 samples.

How the data were processed

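Single-nucleus RNA-seq libraries were made from roots of Medicago truncatula, a model legume, 24 h after inoculation with the nitrogen-fixing rhizobium Ensifer meliloti. Per the labels' protocols, a 1 µL drop of bacteria at an OD600 of 0.02 was placed on the zone of emerging root hairs of 150 seedlings. The seedlings grew with 0.1 µM aminoethoxyvinylglycine, an inhibitor of ethylene synthesis. Segments of 0.5 to 0.7 cm around the drop were chopped, and DAPI-stained nuclei were sorted. Equal numbers of nuclei were loaded per library with the 10x Genomics Chromium 3' chemistry, and each library was sequenced in 2 runs. The experiment was carried out on separate occasions, giving 2 replicates of 1 group. Uninoculated roots were not analysed here, so no value below is a response to the bacteria.

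The deposited matrices hold counts of unique molecular identifiers (UMIs) per feature and barcode, made with Cell Ranger 4.0.0 for replicate 1 and Cell Ranger 5.0.0 for replicate 2, per the file headers. Version and replicate cannot be told apart in this design. The genome build, the handling of intronic reads and the setting that chose the barcodes are not given in the sources used here. Both matrices list the same 44620 features. The files do not pair the identifiers with gene names: the name column repeats the identifier in all 44620 features. The reference table of the assembly MtrunA17r5.0-ANR, with 39590 genes, matched 0 of the identifiers. The 11 gene lists, the cell type markers and the co-detection of infection genes that had been fixed before the data were examined were therefore not run. Clusters keep numbers, with no cell type. For the same reason 4 identifiers are printed, and these were chosen after their values were seen, by the rules given below. Features were sorted by the prefix of their identifiers into 44253 chromosomal, 86 plastid, 73 mitochondrial and 162 unplaced features and 46 features without a gene-style identifier.

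Barcodes with at least 200 detected genes and at most 5% of UMIs from organelle features were kept. Scrublet, run per library in scanpy 1.11.5 with an expected rate of 8%, called 2 barcodes in replicate 1 and 0 in replicate 2. A caller that marks so few has not worked, and no barcode was removed as a doublet. Counts were scaled to 10000 per nucleus and log-transformed. The fixed lists were to be kept out of the clustering genes; in their place, chosen after seeing the files, the chromosomal genes were split at random into 22172 genes that could define clusters and 22081 held-out genes for the tests. From the former, 2000 variable genes were scaled within each replicate and reduced to 30 principal components. A shared-neighbour graph with 20 neighbours was clustered with leidenalg 0.10.2 at a resolution of 0.8. Of 17 clusters, 16 held at least 20 nuclei in each replicate. The remaining cluster held 1 nucleus and was left out.

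Counts were summed per cluster and replicate, since nuclei are not replicates. Held-out genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM scaling. The replicate was a block, because sums of 1 replicate come from 1 library. The filter on low sums, filterByExpr, took the clusters as groups, so a gene could pass through 1 cluster in which it is high. Benjamini-Hochberg adjustment was made over the held-out genes tested, at a threshold of 0.05, for the F test and for each cluster's contrast apart. The F test compared all 16 clusters. In addition each cluster was set against the mean of the log values of the other clusters, weighted by their UMIs. A gene called higher in a cluster may therefore be as high in another cluster. The contrast fixed before the data were examined gave the other clusters equal weights. It was replaced after seeing the data, because clusters with few UMIs weigh in it as much as large ones, and labels shuffled as described below gave between 71 and 133 higher and between 12 and 25 lower genes in cluster 1. The contrast weighted by UMIs was thus chosen after seeing the data, and the counts of the equal weights are among the alternatives. The cluster labels came from the same nuclei as the sums, so the p-values are conditional on those labels. They are relative to the spread of sums between replicates that is left after the block on the replicate. The block takes out a shift of a gene shared by all clusters of a replicate, so this spread leaves it out. The edgeR model shares its estimate of this spread between genes. Very small p-values therefore rest on the shared estimate and not on the sums of 1 gene alone. Counts were also simulated with no cluster effect except in 200 changed genes, drawn from held-out genes with at least 500 UMIs. Every gene was given the same dispersion, and no replicate effect was put in. False calls were counted in the contrast of the changed cluster only. The real counts may depart from these settings, so the rates below hold for the simulation. The test recovered 97% of the 2-fold and 100% of the 4-fold changes in cluster 3, with 1 false call among 4349 genes tested. Recovery of genes with fewer UMIs was not simulated. In cluster 16 the test recovered 2% and 44%, with 8 false calls among 4307 genes tested. For the 2-fold and 4-fold changes the median log2 estimates were 0.995 and 2.03 in cluster 3. They were 0.64 and 1.46 in cluster 16, so the changes in cluster 16 were underestimated. With the real labels shuffled 5 times within replicate and depth, between 74 and 107 genes passed the F test, between 28 and 36 were called higher in cluster 1 and between 33 and 56 lower. The weights by UMIs thus gave fewer higher but more lower calls with shuffled labels than equal weights.

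Shares of nuclei carry 95% Wilson intervals, and levels in CPM, counts scaled to the total of a sum, carry exact Poisson intervals; both cover counting error only. Profiles of clusters were log2(CPM + 10) centred on the mean of all clusters in a replicate, over 7232 held-out genes with at least 100 UMIs. Whole libraries were compared on log2(CPM + 1). The cluster genes printed are those with the highest and the lowest log2 value of any cluster among called genes with the same sign in both replicates and at least 10 UMIs inside and outside the cluster in each. The library genes printed are those with the highest and the lowest log2 ratio between replicates among genes with at least 5000 UMIs. DESeq2 1.42.0, RLE scaling, no filter, no replicate block, other filters on nuclei, other resolutions and other scalings were tried as alternatives fixed beforehand. Sums thinned to 1 depth, the omission of cluster 1, a common UMI minimum of 409, removal of the top 8% of barcodes by Scrublet score, clustering genes from all chromosomal genes and clustering each replicate alone were added after seeing the data.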

Results

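The data describe nuclei from the inoculated root segment of Medicago truncatula 24 h after contact with Ensifer meliloti, in 2 replicate libraries. The deposited matrices held 9016 barcodes with 4300322 UMIs in replicate 1 and 9000 barcodes with 7210046 UMIs in replicate 2. Of these, 6690 nuclei were kept in replicate 1 and 8977 in replicate 2. The kept nuclei had a median of 422 UMIs and 351 detected genes in replicate 1, and of 611 UMIs and 525 genes in replicate 2. The filter on detected genes removed 2326 barcodes from replicate 1 and 0 from replicate 2, whose lowest barcode already held 409 UMIs against 193 in replicate 1. In replicate 2, 23 barcodes exceeded the limit on organelle UMIs.

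The nuclei fell into 16 testable clusters, which differed widely in size. Cluster 1 held 31.5% of the nuclei of replicate 1 (95% Wilson interval 30.4 to 32.7) and 41.5% of those of replicate 2 (40.4 to 42.5). Cluster 2 followed with 16.2% in both replicates, and cluster 3 with 13.1% (12.3 to 13.9) and 10.0% (9.44 to 10.7). Cluster 4 held 9.37% and 8.45%, and cluster 5 held 669 of the 6690 and 655 of the 8977 nuclei. Cluster 6 held 4.72% and 4.76%, and clusters 7 to 16 each held under 4% in either replicate. Cluster 16 was the smallest, with 26 and 24 nuclei. With at least 400 detected genes per nucleus, the largest cluster was another one, which held 0.684% of the nuclei of cluster 1 that remained.

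Clusters 11 and 12 differed most between the replicates in relative terms. Cluster 11 held 1.85% of nuclei in replicate 1 (1.56 to 2.21) and 0.546% in replicate 2 (0.413 to 0.721). Cluster 12 held 1.02% (0.803 to 1.29) and 0.390% (0.280 to 0.542). Over all clusters, 10.3% of nuclei would have to change cluster to make the shares of the replicates equal. Among 1000 draws from identical shares the highest value was 3.61%, so the replicates differed by more than counting error. The value depended on the barcodes kept and the scaling: it was 30.8% with at least 400 detected genes, 32.4% with the same UMI minimum in both replicates and 48.2% with genes scaled over both replicates together. With 2 replicates the spread of a share is known only as the difference between them.

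**Figure D1:**
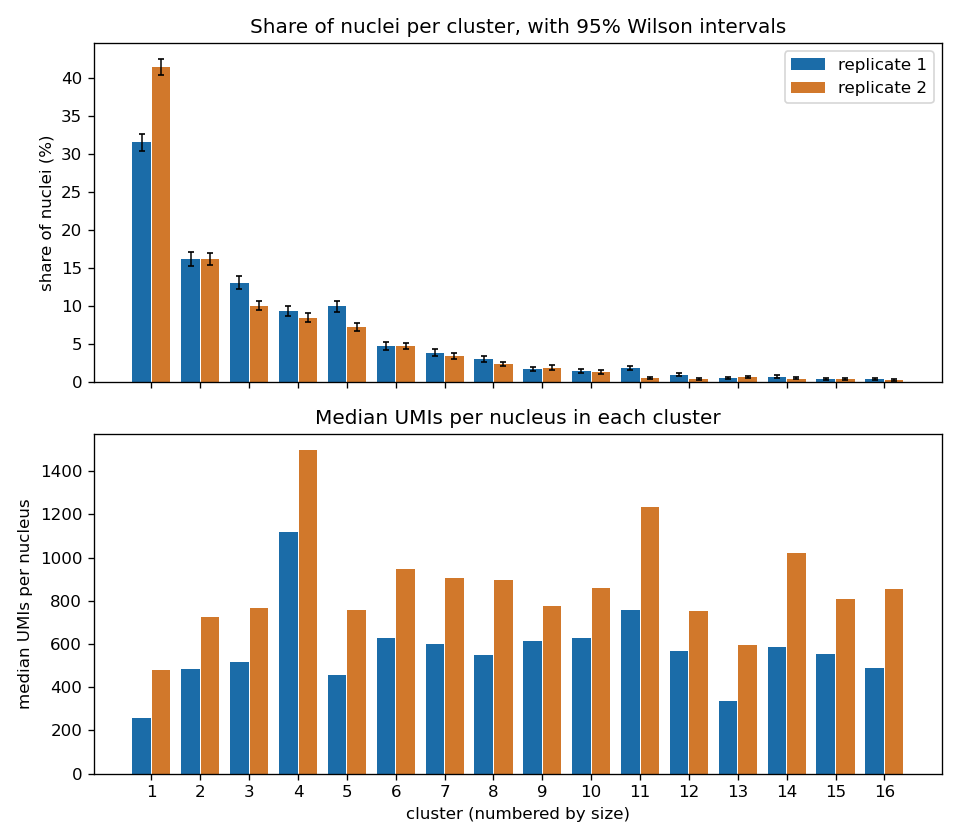
The upper panel plots the share of nuclei in each cluster in percent, with bars for replicates 1 and 2 and 95% Wilson intervals; the lower panel plots the median UMIs per nucleus. Cluster 1 is the largest in both replicates and has the lowest median, 257 and 478 UMIs, while cluster 4 has the highest, 1117 and 1496 UMIs.

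Depth differed between the clusters. Nuclei of cluster 1 had a median of 257 UMIs in replicate 1 and 478 in replicate 2. Those of cluster 4 had 1117 and 1496, and those of cluster 2 had 485 and 727.5. Cluster 11 had 756.5 and 1235, and cluster 13 had 335 and 597. Of the 669 shallowest nuclei of replicate 1, 92.5% (90.3 to 94.3) belonged to cluster 1, as did 745 of the 898 shallowest of replicate 2. It took 0 of the 669 deepest nuclei in replicate 1, with an upper Wilson bound of 0.571%, and 3 of the 897 deepest in replicate 2.

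Whether genes outside the clustering set differed between the clusters was asked of the held-out genes. Of 5254 held-out genes tested, 3316 (63.1%) differed between the 16 clusters (edgeR F test, adjusted p under 0.05). Without a filter on low sums it was 4401 of 14848 genes (29.6%), and without the replicate block 2623 of 5254. The filter used the cluster labels, and with shuffled labels only 4165 to 4535 held-out genes passed it. The share of 63.1% is therefore a share of genes chosen in part by the labels tested. Of the tested genes, 3158 were higher in at least 1 cluster than in the weighted mean of the other clusters, and 1528 of these in exactly 1 cluster. Adjustment was made per cluster, so the threshold of 0.05 does not cover such a union over the 16 clusters. The union was 3888 with equal weights, 3371 with RLE, 3482 with DESeq2 and 4641 without a filter. It was 2442 without the replicate block and 2808 without cluster 1. Of the higher genes, 1398 had an estimated rise of at least 4-fold, 915 of them in exactly 1 cluster. No test against 4-fold was made. A gene counted in exactly 1 cluster may have risen unseen in others, as the simulation recovered only 44% of 4-fold changes in cluster 16. These calls rest on 2 sums per cluster.

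Cluster 3 had 830 higher and 384 lower genes, and 229 of its higher genes lay at least 4-fold above the weighted mean of the other clusters. Cluster 5 had 570 higher and 185 lower genes, cluster 7 had 453 and 172, cluster 6 had 396 and 155, and cluster 8 had 381 and 131. Cluster 11, with 317 higher and 125 lower genes, had 128 at 4-fold or more. Cluster 9 had 127 higher and 38 lower genes. The counts of lower genes depended on the setting: in clusters 3 and 5 to 11 they were more than 1.5 times smaller with equal weights and without the replicate block, at 82 and 174 in cluster 3. DESeq2 instead called more lower genes in cluster 5, 456 higher and 328 lower, and in cluster 6, 337 and 234, and fewer in cluster 11, 412 and 74. The order of the clusters by higher genes depended on the contrast and the depth. With the equal weights fixed beforehand, cluster 4 had 1124 and cluster 3 had 990, and clusters 5, 6, 8 and 9 had 884, 702, 590 and 317; with sums thinned to the smallest, cluster 15 had 61 and cluster 3 had 34. Without the replicate block clusters 5 and 6 had 377 and 242, and without a filter on low sums cluster 3 had 1352.

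Few higher genes of clusters 1, 2 and 4 reached 4-fold. Cluster 1 had 328 higher genes, 31 of them 4-fold or more, and 102 lower ones. Cluster 2 had 213 higher genes, of which 4 reached 4-fold, and 23 lower ones. In cluster 4, 11 of 550 higher genes reached 4-fold. The 102 lower genes of cluster 1 stand against 33 to 56 with shuffled labels, 37 with equal weights and 3 without the replicate block. The higher counts of clusters 1 and 2 were unstable as well: without the replicate block 35 genes were higher in cluster 1 and 35 in cluster 2, DESeq2 called 185 and 84, and the equal weights fixed beforehand called 909 and 945. With RLE, 131 genes were higher in cluster 2.

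The balance of higher and lower genes moved by over 10 percentage points with RLE scaling in 7 clusters. Cluster 4 had 550 higher and 140 lower genes, and with RLE scaling 408 and 193. The balance of cluster 4 turned with DESeq2, to 324 higher and 348 lower genes. It had 248 and 65 without the replicate block, 832 and 119 without a filter, and 1124 and 112 with equal weights. Cluster 10 had 551 and 282, and with RLE 773 and 167. Cluster 12 had 174 and 82, against 266 and 22, and cluster 13 had 160 and 88, against 227 and 23. In cluster 14, 57.8% of the called genes were higher, against 79.7% with RLE. Cluster 15 had 225 and 106, against 306 and 20, and cluster 16 had 204 and 208, against 276 and 28. RLE moved the median log2 value of all tested genes by 0.56 in cluster 15 and by 0.64 in cluster 16. That median was -0.74 and -1.01 with TMM, -0.18 and -0.36 with RLE, and -0.03 and -0.07 with DESeq2. Counts of lower genes in these small clusters are therefore relative to the scaling. Equal weights under TMM raised the share of higher genes among the called genes in all 16 clusters; clusters 10 and 12 to 16 had 666 higher and 123 lower, 224 and 27, 180 and 44, 338 and 99, 229 and 43, and 202 and 92 in turn. DESeq2 called 863, 365, 330, 545, 396 and 376 higher and 150, 15, 17, 67, 11 and 15 lower genes in clusters 10, 12, 13, 14, 15 and 16.

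The highest value among well-counted held-out genes was that of MtrunA17Chr3g0107931 in cluster 15, at a log2 value of 9.73 (SE 0.33) over the other clusters (edgeR, adjusted p = 1.81e-191). It reached 2875 CPM in the cluster (exact Poisson interval 2209 to 3679) against 3.42 CPM elsewhere in replicate 1. In replicate 2 it reached 2816 CPM (2249 to 3482) against 4.75 CPM. The lowest was that of MtrunA17Chr1g0167981 in cluster 16, at a log2 value of -2.87 (SE 0.31, edgeR, adjusted p = 6.88e-19). It stood at 771 CPM (410 to 1318) in the cluster against 5442 CPM elsewhere in replicate 1, and at 953 CPM (604 to 1431) against 5165 CPM in replicate 2. With sums thinned to the smallest the log2 values were 8.46 and -1.45. The median log2 value of all tested genes in cluster 16 was -1.01, and -0.09 with thinned sums.

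Clusters grouped by shared genes. Clusters 3 and 10 shared 333 higher genes, against 87.0 for independent lists, and clusters 3 and 7 shared 246 against 71.6. Clusters 2 and 4 shared 156 against 22.3, and clusters 5 and 8 shared 104 against 41.3. The contrasts of a pair share the sums of the other clusters, so part of each excess may come from those sums. The profile of cluster 4 was the nearest to that of cluster 2 in both replicates, with a Pearson r across genes of 0.71 in each. For clusters 7 and 10 the nearest profile was that of cluster 3 in both replicates. Within a replicate, clusters 15 and 16 had no other cluster above an r of 0.0114. Their sums held only 16871 to 30189 UMIs, so a count of 3 stood at 99.4 to 178 CPM. Low counts alone lower r, and these clusters matched themselves between replicates at only 0.250 and 0.224. The low r therefore does not show that they resemble no other cluster. Between replicates, cluster 15 of replicate 1 correlated at 0.0676 with cluster 16 of replicate 2, and cluster 16 at 0.0716 with cluster 15. These clusters shared 31 higher genes against 8.74 for independent lists, and clusters 10 and 15 shared 58 against 23.6.

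The profiles of the same cluster were then compared between the replicates, across held-out genes, which are not independent replicates. In 15 of the 16 clusters the best match in the other replicate was the same cluster, in both directions. The exception was cluster 2, whose profile in replicate 1 correlated at 0.571 with cluster 4 of replicate 2 and at 0.528 with its own. The correlation of a cluster with itself ranged from 0.187 in cluster 12 to 0.693 in cluster 4. The sums of cluster 12 held 42813 and 30292 UMIs, and those of cluster 4 held 761887 and 1232071. This range may therefore reflect the depth of the sums. The labels came from nuclei of both replicates clustered together, which favours a match of a cluster with itself. When each replicate was clustered alone, 16 clusters were found in replicate 1 and 14 in replicate 2, of which 13 were mutual best matches. The r of these 13 matches had a median of 0.435 and a lowest value of 0.184. Unrelated profiles also give some mutual best matches, and their number was not computed. The adjusted Rand index, which is 1 for identical groupings, was taken between these clusters and the joint labels. It was 0.614 in replicate 1 and 0.633 in replicate 2.

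**Figure D2:**
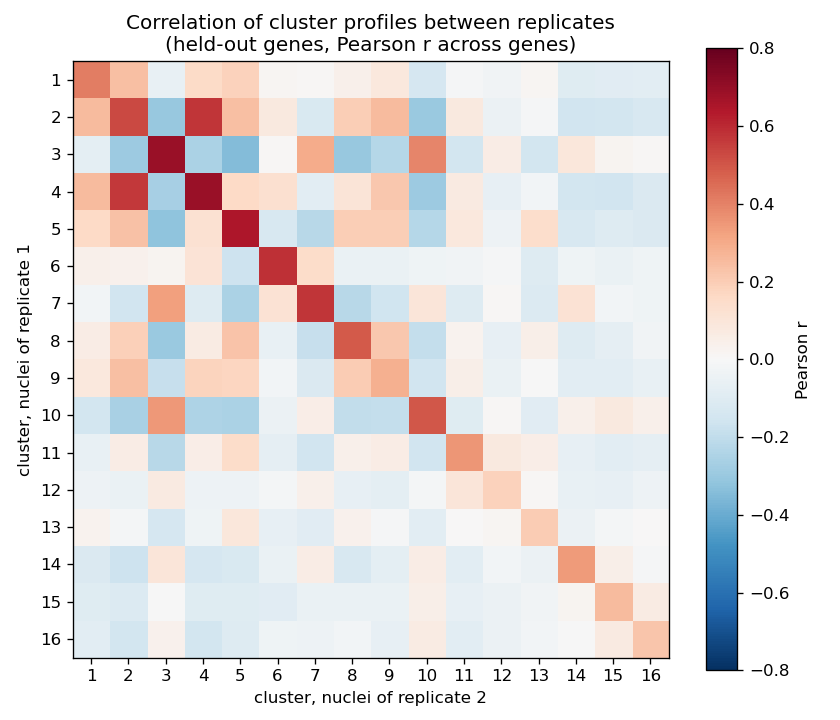
Each square shows the Pearson correlation across held-out genes between a cluster's profile in replicate 1 (vertical axis) and in replicate 2 (horizontal axis), from blue (negative) to red (positive). The diagonal holds the highest value of its row and column in 15 of 16 clusters; off the diagonal, the highest value is the 0.571 of cluster 2 in replicate 1 with cluster 4 in replicate 2.

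Summed over all kept nuclei, the replicates correlated across 30103 genes with a Pearson r of 0.977 and a Spearman rho of 0.968. Of 5584 genes with at least 500 UMIs, 120 differed over 2-fold between the libraries, 74 of them higher in replicate 2 and 46 higher in replicate 1. No test was made, since each library stands alone. MtrunA17Chr7g0226671 stood at 934 CPM in replicate 2 against 151 CPM in replicate 1 and was higher in replicate 2 in all 16 clusters. MtrunA17Chr5g0411151 stood at 479 CPM in replicate 2 against 1086 CPM in replicate 1 and was lower in replicate 2 in 15 of 16 clusters.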

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

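Features outside the tests carried UMIs above the limit that a count of 0 allows. Features without a gene-style identifier took 2237 UMIs in replicate 1 and 5163 in replicate 2. Mitochondrial features took 1820 UMIs (0.0423% of the library) in replicate 1 and 19226 (0.267%) in replicate 2. Plastid features took 2521 UMIs (0.0586%) in replicate 1 and 8181 (0.113%) in replicate 2. Unplaced features took 4919 UMIs (0.114%) in replicate 1 and 10521 (0.146%) in replicate 2. No explanation of these values was tested.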

How the results depend on the processing

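The thinned sums, the omission of cluster 1, clustering genes from all chromosomal genes, the common UMI minimum, the removal by Scrublet score and the clustering of each replicate alone were chosen after seeing the data. So was the contrast weighted by UMIs behind the reported counts per cluster, in place of the equal weights fixed beforehand. The other alternatives were fixed beforehand. The count of held-out genes that differ between clusters stayed within 1.5 times of 3316 under DESeq2, RLE, no filter, no replicate block, the omission of cluster 1 and every other clustering of both replicates together, with 1 exception; it was not computed for a replicate clustered alone. Without a filter it was 4401 of 14848 genes tested, a share of 29.6% against 63.1%. With clusters made from part of the UMIs and tests on the rest it was 1804 of 3446 genes tested. With every sum thinned to 14897 UMIs it was 279 of 345, and 278 genes were higher in at least 1 cluster; fewer genes pass the filter at that depth. Thinned, the higher genes numbered 3, 8, 34, 22, 19, 31, 29, 27, 11, 36, 34, 30, 34, 40, 61 and 55 in clusters 1 to 16 in turn.

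No replicate block left 35, 35, 248, 377 and 242 higher genes in clusters 1, 2, 4, 5 and 6, and the other 11 clusters stayed within 1.5 times. DESeq2 gave 185, 84, 324, 863, 365, 330, 545, 396 and 376 in clusters 1, 2, 4, 10, 12, 13, 14, 15 and 16. RLE gave 131 in cluster 2 and 266 in cluster 12. No filter gave 1352 in cluster 3 and 832 in cluster 4. Equal weights gave 909, 945, 1124, 884, 702, 590 and 317 in clusters 1, 2, 4, 5, 6, 8 and 9. No gene called higher in a cluster was called lower in it under these settings. The cause was not tested for any of these changes. Equal weights raised the median log2 value of all tested genes in every cluster, from a rise of 0.24 in cluster 16 to 0.36 in cluster 11.

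Against the 16 testable clusters reported, 13 were testable with at least 400 genes, with the common UMI minimum and with clusters from part of the UMIs, and 14 to 17 in the other clusterings. Between 14 and 18 clusters of any size were found, and 16 and 14 with replicate 1 or replicate 2 alone. The nuclei that would have to change cluster were 30.8% with at least 400 detected genes, 32.4% with a common UMI minimum, 7.76% with clusters from part of the UMIs and 48.2% with genes scaled over both replicates. The largest cluster held a mean of 36.5%. With 400 genes the largest was another cluster, with a mean of 25.2% and 0.684% of the remaining nuclei of cluster 1. With the common minimum the largest held a mean of 28.8%, from 12.7% of replicate 1 and 44.8% of replicate 2, and with joint scaling 24.4%, from 3.63% and 45.2%; it took in 92.9% and 61.8% of the nuclei of cluster 1. The mean share without replicate 1 or 2 ran from 31.5% to 41.5%. The correlation of the libraries was 0.980 with a pseudocount of 10 and 0.963 over genes with at least 10 counts. The printed cluster genes kept their direction and call in every refit. Without a replicate, values were differences in log2(CPM + 1), not edgeR values, and had no test. MtrunA17Chr3g0107931 then ran from 8.94 to 9.35 and MtrunA17Chr1g0167981 from -2.82 to -2.44. Thinned sums gave these genes edgeR log2 values of 8.46 and -1.45 against 9.73 and -2.87. With 1 library no residual degrees of freedom among samples are left. The alternatives for the gene lists and the depth deciles for co-detection were not run, because the reference used here paired no identifier with a name.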

Other observations

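The bounds of the tests below were set before their results were seen, after the patterns themselves had been noticed; the test on left-out clusters was added afterwards. No biological explanation was tested for the first and second patterns, because the design has 1 group.

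Cluster 1 was the largest and the shallowest cluster in both replicates at the filter of 200 detected genes. Genes higher in clusters 2 to 16 lay in cluster 1 at a median of 0.976 of their level in the sum of those clusters, with a range from 0.898 to 1.14 over the clusters, while the same median ran from 0.597 to 0.774 in clusters 2 to 8 and 10, whose sums gave no ratio of 0. The ratio meets the bound set for free RNA, but a mixture of shallow nuclei would give it too. Cluster 1 had 328 higher genes (28 to 36 with shuffled labels, 35 without the replicate block), 31 of them 4-fold or more. Its profile matched itself best between replicates (r = 0.410). Neither result can decide about a plain pool of the other clusters. A pool adds counts, so it lies above a mean of log values for genes high in few clusters. Profiles were centred on the unweighted mean of all clusters, so a pool could match itself too. Of 9213 nuclei of clusters 2 to 16 thinned to the median depth of cluster 1, 13.5% joined the cluster holding most of it. The share ran from 5.00% in cluster 15 to 42.7% in cluster 13, and 13.5% lies between the bounds set. That clustering found 13 clusters, and the one counted held 78.2% of cluster 1. For cluster 1, free RNA, shallow nuclei and nuclei of its own kind therefore cannot be told apart.

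The 120 genes that differed over 2-fold between the libraries were not accounted for by cluster shares: giving both libraries the same shares took 5.82% off their median absolute log2 ratio, from 1.21 to 1.14. The median such gene differed in the same direction in 14 of the 16 clusters, the bound set for a shift across the whole library, but these clusters are parts of the sums that chose the genes. With genes chosen instead for each cluster by a difference over 2-fold in the sum of the other clusters, a median of 89.9% differed in the same direction in the left-out cluster (77.2% to 99.0%), against 62.7% of genes with smaller differences. Such a shift may come from the experiment, the library or the Cell Ranger version, and with 1 library per version the version cannot be told apart from the replicate.

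Held-out genes with neighbouring identifiers tended to peak in the same cluster, as did 90 of 310 pairs with consecutive identifiers. A share of 7.84% was the mean, and 12.3% the highest value, in 1000 shuffles within chromosomes. The excess at a distance of 3 identifiers was 36.1% of that at 1 and above every shuffle, which argues against reads counted across the border of adjacent genes as the whole cause. At a distance of 5 identifiers 8.52% of pairs had the same peak, within the shuffles, which argues against long stretches of like expression. Short runs of related genes, or reads shared within such runs, may remain and were not tested, because neither positions nor sequences were used and the order of identifiers was taken as the order of genes.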
